A study of Homo sapiens with 2 samples.

How the data were processed

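Total RNA from 2 MRC-5 samples, labelled with Cy3, was hybridised on 2 two-colour oligonucleotide arrays against the mix2 reference, labelled with Cy5, per the labels. Both arrays had the same dye orientation, so a dye effect of a probe does not cancel in their mean. Per the submitters' processing notes, images were read with Agilent Feature Extraction, whose version is not given in the sources used here. The deposited table holds the authors' processed log2 ratio of each probe on each array, 41000 probes in all. The scanner's intensities were not used here, and the authors' background correction, within-array normalization, centring, spot filters and genome build are not given in the sources used here.

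The scale was inferred from the values. They ran from -7.8 to 6.17 on array 1 and from -7.83 to 5.52 on array 2, while log10 of a ratio of 16-bit intensities cannot exceed 4.82, so log10 was excluded and base 2 was assumed; a natural log cannot be excluded. The deposited columns had medians of -0.056 and -0.077 and means of 0.0074 and -0.0043, and no value was missing or exactly 0. The direction of the ratio stays unstated. Agilent's software gives Cy5 over Cy3, which would be mix2 over MRC-5, but it writes log10 values, which these are not. The wording of the titles and design text gives MRC-5 against mix2, and positive values were therefore read as likely higher in MRC-5. No genome coordinates are given because no build is named.

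Probes were named from the platform annotation supplied with the data. It paired 29341 probes with 1 gene symbol and 33 with several, and 11626 probes had no entry and are unnamed here. Gene IDs of 29298 of the single-gene probes were found in the RefSeq gene table, whose symbols were used. Probes of 1 gene were averaged per array. Of 18646 symbols, 54 (XIST, TSIX and Y-linked genes) were left out, which gave 18592 genes. Of these, 7597 had 2 or more probes, and in 3060 of those the probe means differed in sign.

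The test was limma's lmFit with an intercept and eBayes, the mean log2 ratio against 0, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, fitted once to all probes and once to all genes. It has 1 residual degree of freedom per gene and a prior of 1.13 degrees of freedom with a prior SD of 0.04. Counts of genes at least 2-fold (log2 of 1) on both arrays were made without a test. The 32 gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated from the residuals, which have 1 degree of freedom. The estimated setting also refers its statistic to 1 degree of freedom, which leaves it little power whatever the correlation. Camera compares a list with all other genes. A list needed 3 measured members, and list symbols were updated through the RefSeq synonyms; members with no named probe were not analysed here.

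The comparisons, tests, gene lists and rule for named genes were fixed before the data were examined. Named genes were the 15 highest and 15 lowest that passed the adjusted p and were at least 2-fold the same way on both arrays, leaving out placeholder symbols, and from each list up to 4 members with the largest absolute mean among those that passed, or 2 where none did. Other list members are named as examples or because they did not pass, and the olfactory receptor genes, the gene families and the genes with several probes in the closing part were chosen after their values were seen. The lists were anterior, middle and posterior HOX genes, lung mesenchyme regulators, skin and limb mesenchyme regulators, collagens, elastic fibre and matrix glycoproteins, proteoglycans and hyaluronan, matrix proteases and inhibitors, contractile genes, TGF-beta response genes, BMP and TGF-beta ligands, WNT genes, the IGF axis, FGF, PDGF, HGF and VEGF factors, cell cycle genes, p53 targets, secreted inflammatory factors, interferon-stimulated genes, antigen presentation, imprinted genes, cholesterol synthesis, glycolysis and hypoxia, amino acid and endoplasmic reticulum stress, oxidative phosphorylation, ribosomal proteins, pluripotency, and markers of epithelium, endothelium, immune cells, pericytes and adipocytes, and neural cells.

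The test was run on simulated data for this comparison of 18592 genes with known changes. It called 80% of 50 genes changed by 4-fold, 84% of 50 changed by 8-fold, 2% of 50 changed by 2-fold and 0% of 50 changed by 1.5-fold, with 2 false calls; 62 unchanged genes were 2-fold on both simulated arrays. The simulated SD between arrays had a median of 0.038 and a 99th percentile of 1.49, against 0.039 and 0.803 in the deposited values, so the simulated spread of the noisiest genes was the larger. Few genes changed in that simulation, which makes the adjustment stricter. A further simulation had as many changed genes as were called (12418 of 18592), at their fitted sizes. There the test called 75.0% of those under 1.5-fold, 93.1% from 1.5-fold to 2-fold and 97.1% at 2-fold or more. Of 10288 calls, 162 were false. The changed genes were those this test had called, so recovery is partly built in. All others had a true log2 ratio of 0 and independent noise. With no dye effect or background offset in it, that simulation does not give the false call rate of the deposited data. A simulated shift of 1 in the cell cycle list gave a camera adjusted p of 1.6e-06, and 0 other lists were called. Genes were drawn independently there, so it cannot show how often lists of correlated genes are called falsely. The alternatives were median centring, scaling of the arrays, robust eBayes, a test against 1.5-fold, other ways to join probes, log10 values, camera on ranks, each array alone and, added after the data were seen, natural logs, genes with several probes and a zero point at the olfactory receptor genes. Analyses used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.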

Results

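Gene expression in MRC-5 cells was compared with that in a mixed reference, mix2, on 2 two-colour oligonucleotide arrays. MRC-5 is a human lung fibroblast line. The reference was a mixture of CCD-1079Sk, a human skin fibroblast line, and IMR90, another human lung fibroblast line, in proportions that the labels do not give. The question was how expression in MRC-5 differs from that mixture. On each array an MRC-5 sample carried the Cy3 dye and mix2 carried Cy5. Each array gave a log ratio for 41000 probes, with no missing value, and 18592 named genes entered the gene-level comparison. The values are intensity ratios with no signal levels beside them, so the brightness behind each ratio is unknown and the number of arrays limits the precision. The labels do not say whether the MRC-5 samples came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The mix2 channel counted as 1 control sample, so the tests leave out the control's own spread.

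The sign of the deposited ratios is not stated. The series title and design text present MRC-5 compared with mix2, and the sample titles name MRC-5 first, so positive values were read as likely higher in MRC-5. The scanner software's own ratio, Cy5 over Cy3, would run the other way. Every direction below rests on that reading and would turn as a whole if the ratio ran the other way. Values are mean log2 ratios ± SD over the 2 arrays, with an SD that rounds to 0 left out and captions giving means alone. The SD covers arrays and not the probes of a gene, whose means lay more than 2 log2 units apart for HOXC10, HOXB7, CXCL12, PTGIS, COL14A1, COL4A5, COL4A6, SKIL and STMN2, among others. The log base is not stated either; base 2 was used, and a natural log would make each fold larger.

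The arrays ranked genes alike. Spearman's rho between them was 0.892 across probes and 0.906 across genes. Pearson's r was 0.92 across probes and 0.935 across genes, where genes are not independent replicates. The arrays shared the reference and the dye orientation, so a constant effect of a probe or dye would raise these values. The median SD between arrays was 0.039 per gene, against an SD of 0.71 for the mean ratio across genes. In the plot of the arrays against each other, genes far from 0 lay along the diagonal.

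**Figure D1:**
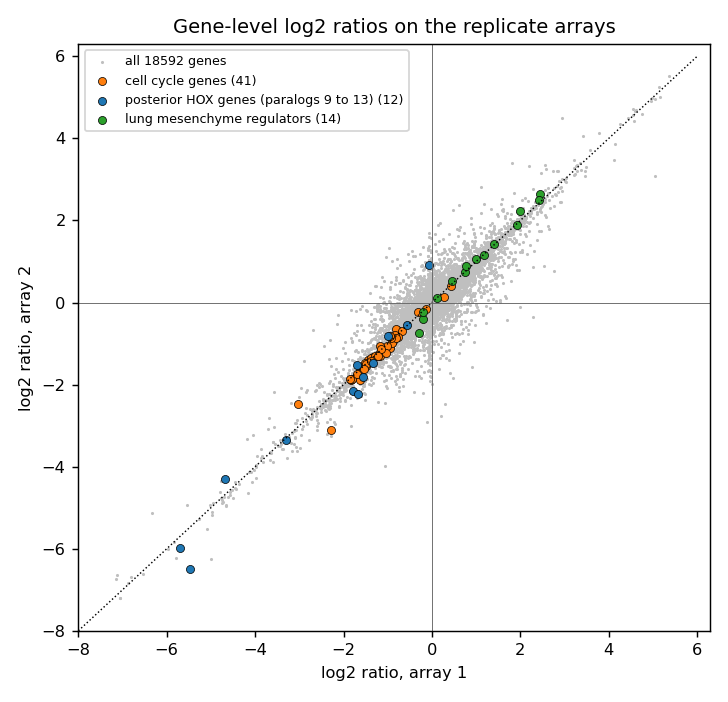
Log2 ratio of each gene on array 1 (x axis) and array 2 (y axis), with all 18592 genes in grey and 3 gene lists coloured; the dotted line marks equal values. By the mean of both arrays, the 12 posterior HOX genes reach -5.98 and the 14 lung mesenchyme regulators reach 2.55, and 39 of 41 cell cycle genes fell below 0 past the test.

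Ratios to the mixed reference were at least 2-fold on both arrays for 1548 genes, of which 737 were higher and 811 were lower in MRC-5. Of these genes, 12 missed limma's adjusted p of 0.05. A single gene, FEZF2, named after its values were seen, was 2-fold down on array 1 and 2-fold up on array 2, and 0 genes showed the reverse. Both arrays had the same dye orientation, so a dye effect of a probe would repeat on both. Agreement of the arrays therefore does not separate dye from cells. Among genes with 2 or more probes, 203 had every probe at 2-fold the same way. The lower side held the larger ratios, with 47 genes at or below -4 against 15 genes at or above 4. In limma's moderated test of the mean ratio against 0, 12418 genes passed an adjusted p of 0.05 (5440 higher, 6978 lower), and 66.7% of them were under 1.5-fold in size. When the test asked for a change beyond 1.5-fold, 1823 genes passed, 894 higher and 929 lower. The balance of directions depended on the zero point. With each array shifted so that the median of the olfactory receptor genes was 0, 82.5% of past genes and 77.7% of 2-fold genes were higher, against 43.8% and 47.6% as deposited. That shift was 0.36 on array 1 and 0.39 on array 2, so small negative ratios turn positive under it. Counts under this shift, called the shifted zero point, are given beside each list whose counts it changes. The shift was read from genes that fibroblasts are not known to express. Whether it also applies to bright probes is unknown, so these counts show how far a list depends on the zero point and are not preferred.

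The genes furthest below the reference lay more than 5 log2 units under it. EMX2, a homeobox transcription factor of trunk and urogenital tissue, lay at -6.88 ± 0.34 (SD, n = 2), and its antisense neighbour EMX2OS at -7.14 ± 0.10. The chemokine CXCL14 was at -7.13 ± 0.10, the retinaldehyde dehydrogenase ALDH1A1 at -6.95 ± 0.29, and the small heat shock protein HSPB3 at -6.85 ± 0.03. APCDD1, a WNT inhibitor of skin, was at -6.75 ± 0.08, and DMKN, a secreted protein of epidermis, at -6.58 ± 0.06. HOXA11-AS, HOXD10 and HOXC9 were at -6.01 ± 0.30, -5.98 ± 0.71 and -5.84 ± 0.19. The scavenging chemokine receptor ACKR4 was at -5.83, the limb and skin regulator TBX15 at -5.62 ± 0.89, and the muscle ubiquitin ligase TRIM63 at -5.31 ± 0.31. CTAG1A (-5.99 ± 0.03) and CLEC18A (-5.73 ± 0.84) have near-identical copies that the probes may not separate. All 15 rested on 1 probe each, with limma adjusted p between 0.0073 and 0.0126.

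The genes furthest above the reference lay more than 4 log2 units over it. They were led by CABP7, a calcium-binding protein of brain, at 5.44 ± 0.11, TEX12, a meiotic protein, at 5.20 ± 0.08, and the adhesion receptor ADGRL3 at 5.07 ± 0.10. CGB1, a chorionic gonadotropin subunit with near-identical copies, lay between ADGRL3 and ATXN3L, the latter at 4.99 ± 0.01, SLC45A4 at 4.94 ± 0.02, the protease inhibitor A2M at 4.65 ± 0.06 and RPA4 at 4.63 ± 0.12. The non-coding transcripts LINC02645, LINC01120 and PLCE1-AS2 were at 4.66 ± 0.11, 4.64 ± 0.05 and 4.56 ± 0.02, and FAM216B was at 4.49 ± 0.10. The globin genes HBD and HBG1 were at 4.46 ± 0.04 and 4.31 ± 0.07, each with 2 probes in accord, although globin genes share sequence. TRHDE was at 4.06 ± 1.40, a wide spread. Of these 15 genes, 13 rested on 1 probe. Among the probes at or above 3 on both arrays, 56 had other probes for the same gene, and those other probes had a median of 0.089; for the 76 such probes at or below -3 the median was -1.42.

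Posterior members of the HOX family, transcription factors whose expression in fibroblasts follows position in the body, were lower in MRC-5. Of 12 measured posterior members (paralogs 9 to 13), 11 were lower, 9 of them by at least 2-fold on both arrays, and 1 did not pass. HOXD10 and HOXC9 led, followed by HOXC10 at -4.49 ± 0.28 and HOXD11 at -3.32 ± 0.03; HOXD12 did not pass at 0.42 ± 0.70. The posterior list was lower relative to other genes in limma's camera test (median -1.82, adjusted p = 0.00447 over 32 lists). With an estimated correlation, a setting with 1 degree of freedom and so little power, its adjusted p = 0.739. Of 11 anterior members (paralogs 1 to 5), 5 were higher and 4 lower, or 6 and 1 with the shifted zero point; HOXA2 was at 1.00 ± 0.02, HOXB5 at 0.96 ± 0.03 and HOXB2 at 0.92 ± 0.03, whereas HOXD3 was at -1.64 ± 0.37. Among 6 middle members (paralogs 6 to 8), HOXB6 was higher at 1.36 ± 0.01 and HOXB7 at 0.72 ± 0.01, although the probes of HOXB7 lay on opposite sides of 0, and HOXD8 was lower at -2.37 ± 0.13. The anterior and middle lists did not pass camera, with adjusted p of 0.483 and 0.753. The HOXA cluster was represented by 1 gene; its other members were not analysed here.

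**Figure D2:**
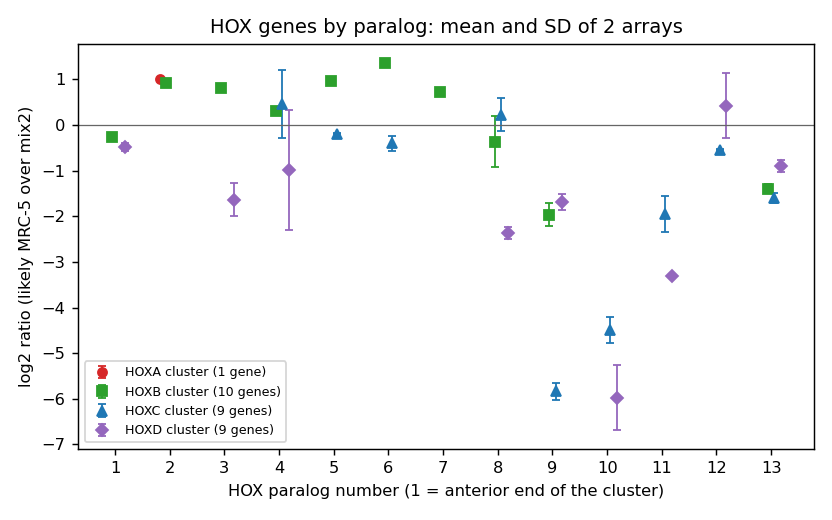
Mean log2 ratio of each measured HOX gene (y axis) by paralog number (x axis), with symbols for the 4 clusters and error bars showing the SD of 2 arrays. HOXC9 and HOXD10 lie lowest, at -5.84 and -5.98, while HOXB2, HOXB5 and HOXB6 lie between 0.92 and 1.36.

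Regulators of lung mesenchyme were higher in MRC-5 as a group, although the reference also contained a lung line. Of 14 measured, 11 rose and 1 fell, or 12 and 0 with the shifted zero point, 7 of them by at least 2-fold on both arrays. The homeobox factor MEOX2 was at 2.55 ± 0.15, WNT2, a ligand of early lung development, at 2.46 ± 0.06, FGF10, the growth factor of lung branching, at 2.11 ± 0.18, and TBX2 at 1.91 ± 0.02. FOXF1 and TBX5 were at 1.41 ± 0.02 and 1.17 ± 0.02. TBX3 fell, at -0.22 ± 0.01, a value that the shifted zero point would turn and whose probes lay on opposite sides of 0, and TBX4 did not pass at -0.52 ± 0.32. The list had a camera adjusted p of 0.00376, which became 0.0473 with the shifted zero point and an adjusted p = 0.739 with an estimated correlation. Most members have 1 probe. The few with several probes on one side of 0 had a median of 0.118 (camera adjusted p = 0.62). Regulators of skin and limb mesenchyme were divided, with 7 of 16 lower and 4 higher, or 6 and 7 with the shifted zero point (camera adjusted p = 0.515). EMX2 and TBX15 were lowest, SHOX2 was at -2.79 ± 0.13 and TWIST2, a regulator of dermal fibroblasts, at -2.71, whereas PRRX1 and MSX2 were higher at 1.28 ± 0.09 and 1.16 ± 0.04.

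Cell cycle genes were lower in MRC-5 almost throughout the list. Of 41 measured, 39 fell and PCNA rose (0.41 ± 0.02); AURKA did not pass, at 0.20 ± 0.08. The proliferation antigen MKI67 was at -2.75 ± 0.39, the centromeric histone CENPA at -2.71 ± 0.58, and the mitotic genes KIF2C and BUB1 at -1.87 ± 0.01 and -1.87 ± 0.04. Among genes of DNA replication, MCM2 was at -1.58 ± 0.05 and CDC45 at -1.52 ± 0.04, while MCM4 (-0.27 ± 0.06) and TYMS (-0.15 ± 0.01) fell less and would turn with the shifted zero point. In all, 26 members were at least 2-fold lower on both arrays. With the shifted zero point 37 members passed below 0 and 3 above. The list median was -1.17, with a camera adjusted p of 4.79e-08, an adjusted p = 0.739 with an estimated correlation and an adjusted p = 0.0712 among genes with several probes on one side of 0. Of 21 p53 targets and cell cycle inhibitors, 8 rose and 9 fell, or 13 and 3 with the shifted zero point (camera adjusted p = 0.684): PLK2 was at 1.08 ± 0.01 and RRM2B at 0.77, while CDKN2A, which encodes p16, was at -1.04 ± 0.02.

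Interferon-stimulated genes were also lower in MRC-5. Of 27 measured, 22 fell and 3 rose, or 20 and 3 with the shifted zero point, and 16 were at least 2-fold lower on both arrays. OASL, an antiviral protein, was at -4.13 ± 0.21, the chemokine CXCL11 at -3.47 ± 0.03, XAF1 at -2.50 ± 0.03 and IFIT2 at -2.42 ± 0.10. IFITM1, IFI27 and IRF1 rose, at 0.51 ± 0.02, 0.45 ± 0.02 and 0.28 ± 0.04. The list median was -1.13 and its camera adjusted p was 0.000185, or an adjusted p = 0.739 with an estimated correlation. Of 13 antigen presentation genes, 8 fell and 3 rose, or 2 and 9 with the shifted zero point, and none reached 2-fold on both arrays, with CIITA at -0.78 ± 0.11 and PSME2 at 0.59 ± 0.01 (camera adjusted p = 0.371). The list of secreted inflammatory factors also held genes whose products are not secreted, such as PTGS2, NFKBIA and ICAM1. Of its 29 measured members, 15 fell and 8 rose, or 9 and 14 with the shifted zero point (camera adjusted p = 0.561). The stromal chemokine CXCL12 was at -3.72 ± 0.20, CXCL1 at -2.14 ± 0.01 and the prostacyclin synthase PTGIS at -1.83, while the neutrophil chemokine CXCL8 was higher at 1.81 ± 0.43.

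Genes of cholesterol synthesis were lower in MRC-5. Of 15 measured, 14 fell, 7 of them by at least 2-fold on both arrays (12 lower and 2 higher with the shifted zero point), and NSDHL did not pass at -0.11 ± 0.04. HMGCS1, an early enzyme of the pathway, was at -2.47 ± 0.08, MVD at -1.83 ± 0.08, LSS at -1.53 ± 0.07 and DHCR7 at -1.51. The list median was -0.90, with a camera adjusted p of 0.000145 and an adjusted p = 0.739 with an estimated correlation. Glycolysis and hypoxia genes fell in 15 of 25 cases and rose in 6, or 9 and 9 with the shifted zero point, with ADM at -1.34 ± 0.01 and ENO2 at -1.17 ± 0.01 (camera adjusted p = 0.223). Genes of amino acid supply and endoplasmic reticulum stress rose in 14 of 23 cases and fell in 4, or 19 and 1 with the shifted zero point (camera adjusted p = 0.0156, and adjusted p = 0.739 with an estimated correlation). The members that rose most make or import amino acids: asparagine synthetase ASNS was at 1.35 ± 0.01, the cystine transporter SLC7A11 at 1.32 ± 0.03 and the serine synthesis enzyme PSAT1 at 1.17 ± 0.02. Oxidative phosphorylation genes (15 of 30 higher, 6 lower, camera adjusted p = 0.0716) and ribosomal protein genes (15 of 35 higher, 12 lower, camera adjusted p = 0.316) held no member that was 2-fold on both arrays. With the shifted zero point these counts were 26 higher and 0 lower, and 25 higher and 2 lower.

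Matrix genes with large ratios lay on both sides. Of 25 collagen genes, 16 rose and 6 fell, or 20 and 4 with the shifted zero point, and the list was higher by camera (median 0.39, adjusted p = 0.0168, and adjusted p = 0.739 with an estimated correlation), a call that was lost with that zero point. COL14A1 was at 1.99 ± 0.02, and the basement membrane chains COL4A6 and COL4A5 were at 1.75 ± 0.17 and 1.65 ± 0.03, while COL8A2, COL11A1 and COL21A1 were at -2.97 ± 0.07, -2.68 ± 0.04 and -2.64 ± 0.06. Among 31 elastic fibre and matrix glycoprotein genes, 13 rose and 12 fell, or 18 and 10 with the shifted zero point: FBLN2 was at -3.31 ± 0.06 and the matricellular protein THBS2 at -3.25 ± 0.03, whereas EFEMP1 was at 2.04. Of 23 proteoglycan and hyaluronan genes, 10 rose and 8 fell, or 13 and 8 with the shifted zero point, with PRELP at -2.52 ± 0.13, ASPN at -2.43 ± 0.13 and versican, VCAN, at 1.77 ± 0.01. Of 26 matrix proteases and inhibitors, 10 rose and 11 fell, or 15 and 8 with the shifted zero point: cathepsin K, CTSK, was at -3.99 ± 0.02, MMP11 at -3.67 ± 0.01, MMP3 at -2.77 ± 0.04, and MMP10 at 2.97 ± 0.32. Contractile genes held no member at 2-fold on both arrays, with 5 of 17 higher and 7 lower, or 11 and 2 with the shifted zero point; DES was at -0.76 ± 0.13 and TAGLN at 0.53 ± 0.01. The glycoprotein, proteoglycan, protease and contractile lists had camera adjusted p of 0.878, 0.862, 0.951 and 0.961.

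Several growth factor genes were higher in MRC-5. Of 26 genes for FGF, PDGF, HGF and VEGF factors and receptors, 12 rose and 7 fell, or 17 and 1 with the shifted zero point, and all 7 that reached 2-fold on both arrays were higher. FGF9 was at 2.09 ± 0.04, PDGFD at 1.69 ± 0.05, FGF7, a factor that fibroblasts supply to epithelium, at 1.65 ± 0.02 over 4 probes, and HGF at 1.53 over 3 probes. The list had a camera adjusted p of 0.0493, which was lost after centring each array on its median, with camera on ranks, with the median over probes and with the shifted zero point, and an adjusted p = 0.739 with an estimated correlation. TGF-beta response genes rose in 11 of 16 cases and fell in 2, or 13 and 2 with the shifted zero point (median 0.44, camera adjusted p = 0.0106, and adjusted p = 0.739 with an estimated correlation), a call that was lost with that zero point. SKIL, at 1.75 ± 0.13, and ID1, at 1.22 ± 0.02, were the only 2 members at 2-fold on both arrays. The 3 members that did not pass included SMAD7, at 0.03 ± 0.04. BMP and TGF-beta ligands, receptors and antagonists were 8 of 21 higher and 8 lower, or 11 and 5 with the shifted zero point (camera adjusted p = 0.653): BMP2 and BMP4 were at 2.30 ± 0.02 and 1.72 ± 0.01, and INHBB at -3.09 ± 0.18. In the WNT list, 15 of 23 rose and 6 fell, or 17 and 5 with the shifted zero point (camera adjusted p = 0.0562). WNT2B was at 3.29 ± 0.06, and the secreted WNT antagonists SFRP4 and DKK1 were at -3.19 ± 0.13 and -3.13 ± 0.01. Of 17 IGF axis genes, 6 rose and 7 fell, or 10 and 4 with the shifted zero point (camera adjusted p = 0.878): the binding proteins IGFBP6 and IGFBP3 were at -2.14 ± 0.01 and -2.03 ± 0.01, and IGFBP7 at 1.40 ± 0.03. Of 19 imprinted genes, 6 rose and 8 fell, or 11 and 2 with the shifted zero point (camera adjusted p = 0.961), with MEST at 2.10 ± 0.03 and DLK1 at 1.18 ± 0.01.

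**Figure D3:**
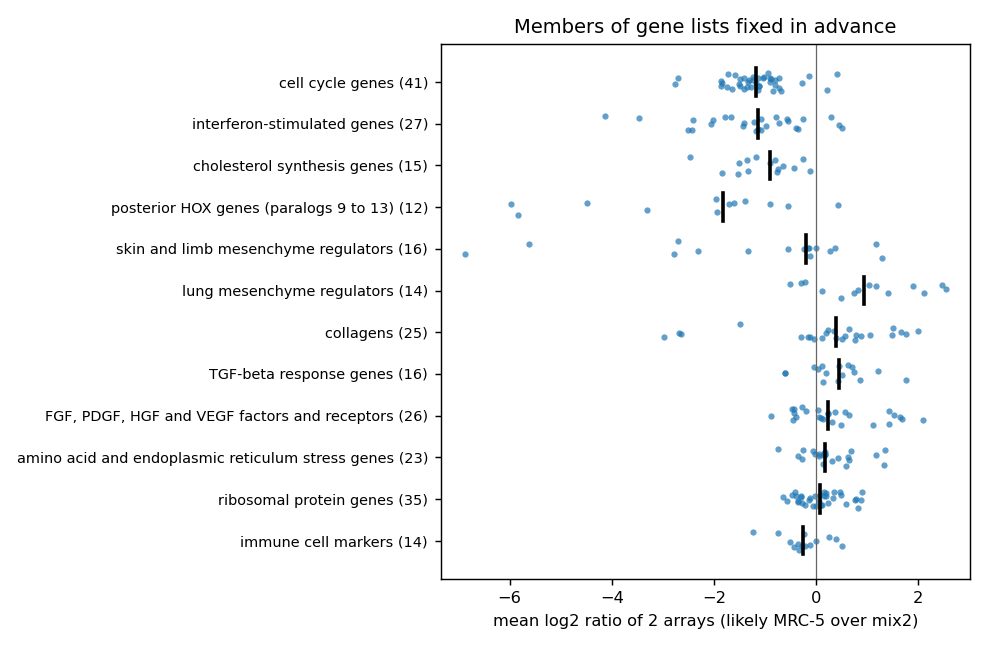
Mean log2 ratio over 2 arrays (x axis) of each measured member of 12 gene lists (rows, with the number of members); points are genes, scattered vertically for visibility, and black bars are list medians. The medians are -1.17 for cell cycle genes, -1.13 for interferon-stimulated genes, -0.90 for cholesterol synthesis genes and 0.93 for lung mesenchyme regulators.

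Lists of markers of other cell types had medians somewhat below 0, and so did the olfactory receptor genes, which fibroblasts are not known to express. The 114 measured olfactory receptor genes, a family chosen for this after the values were seen, had a median of -0.37, and 76 of them passed the test on the lower side and 2 on the upper. Of 16 epithelial and keratinocyte markers, 11 fell and 2 rose, or 6 and 3 with the shifted zero point (median -0.52, camera adjusted p = 0.068); keratin KRT19 was at -5.03 ± 0.09, EPCAM at -1.59 ± 0.13 and KRT18 at 1.12 ± 0.01. Neural and Schwann cell markers fell in 8 of 13 cases and rose in 2, or 4 and 3 with the shifted zero point (median -0.44, camera adjusted p = 0.118). STMN2 was at -4.49 ± 0.04, the mean of probes at -7.81 and -1.16. Of 13 endothelial markers, 5 fell and 2 rose, or 1 and 6 with the shifted zero point (camera adjusted p = 0.581), with the receptor TEK at 2.18 ± 0.02 and EMCN at -1.95 ± 0.03. Immune cell markers fell in 9 of 14 cases and rose in 1, or 3 and 5 with the shifted zero point (median -0.26, camera adjusted p = 0.179), and pericyte and adipocyte markers fell in 5 of 14 and rose in 3, or 3 and 5 with that zero point (camera adjusted p = 0.961). Pluripotency genes fell in 7 of 15 cases and rose in 0, or 3 and 4 with that zero point (median -0.37, camera adjusted p = 0.316), with KLF4 at -2.40 ± 0.09 and MYC at -0.73 ± 0.16.

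The counts adjusted over the list alone were the same as those over all genes in 23 of the 32 lists. In the other 9, the counts adjusted over the list alone were 2 higher and 39 lower for cell cycle genes, 3 and 23 for interferon-stimulated genes, 17 and 7 for collagens, 10 and 10 for proteoglycans, 15 and 7 for WNT genes, 9 and 9 for p53 targets, 17 and 13 for ribosomal protein genes, 2 and 12 for epithelial markers, and 0 and 5 for pluripotency genes. The camera direction was up for the middle HOX, elastic fibre, proteoglycan, contractile, IGF and imprinted lists while their medians and means lay below 0, and for the BMP and TGF-beta list while its mean did; none of these passed. Among genes with several probes on one side of 0, 0 of 27 lists passed camera in limma, and 6 had an unadjusted p under 0.05.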

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

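The alternatives at natural logs, with several probes per gene and with the olfactory receptor zero point were chosen after seeing the data. Within 1.5 times of the reported counts stayed those of probes (25415 as reported, 11925 positive and 13490 negative) and genes past the test with median centring, array scaling and robust eBayes, of 2-fold genes with centring and scaling, and of past and 2-fold genes with the median over probes. Against 1.5-fold, 4174 probes (2542 positive, 1632 negative) and 1823 genes (894 positive, 929 negative) passed. Taking the probe with the largest ratio gave 2449 genes at 2-fold, 1372 of them positive. Reading the values as log10 gave 8478 (3844 positive, 4634 negative) and as natural logs 2937 (1460 positive, 1477 negative). Each array alone, which allows no test, gave 1848 to 1954 genes at 2-fold, 896 to 901 positive and 952 to 1053 negative; counts by p and by list could not be had from 1 array. Genes with 2 or more probes on one side of 0 left 3802 of 4003 past the test (1739 positive, 2063 negative), fewer by construction, and 0 of 27 lists by camera (6 at an unadjusted p under 0.05); 203 genes had every probe at 2-fold (92 positive, 111 negative). With the olfactory receptor genes at 0, a shift of 0.36 on array 1 and 0.39 on array 2, the split of past genes was 10787 positive and 2280 negative, and of 2-fold genes 1726 and 496. List medians of cell cycle (-0.80), interferon-stimulated (-0.76), cholesterol (-0.53) and posterior HOX genes (-1.45) stayed below 0 there. Of 152 named genes, 35 missed the test against 1.5-fold, CENPA (adjusted p 0.0826), TRHDE (0.164) and CXCL8 (0.111) among them; with the olfactory zero point 5 were lost, and TAPBP, also no longer past the test, moved from -0.31 ± 0.01 to 0.0684. MYC was lost with the median over probes (adjusted p 0.0595). Of 9 lists, 0 passed camera (limma) with an estimated correlation, and 0 had an unadjusted p under 0.05 (lowest 0.132). With 1 residual degree of freedom that setting had little power, so it does not show that correlation between genes undid a call. The cholesterol list had an estimated correlation of -0.029, under the preset 0.01, yet its camera p went from 9.05e-06 to 0.132. Camera on ranks and the median over probes each kept 8, losing the growth factor list, and centring called 10, losing that list and adding oxidative phosphorylation genes and epithelial markers. The olfactory zero point called 11, losing it with collagens and TGF-beta response genes and adding those lists with glycolysis, pluripotency and neural lists. There the glycolysis, pluripotency and neural medians were -0.023, 0.0062 and -0.070, all near 0. The oxidative phosphorylation and epithelial medians were 0.46 and -0.15. Such calls are relative to the other genes, since 82.5% of past genes were positive with that zero point. Where construction does not show it, the cause was not tested. No probe was exactly 0, so that filter was not run. No paired analysis was possible because the series has a single group. Signal over background is unknown, which limits every ratio of dim probes.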

Other observations

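Of the tests in this part, those on olfactory receptor genes, their zero point and genes with several probes on one side of 0, and the gene families and several-probe genes, were chosen after the values were seen; the HOX test was fixed before the data were examined, and the tests on other probes of the same gene before their result was seen. Genes with 2 or more probes that all lay at least 2-fold the same way do not rest on a single probe, although their probes can differ in size, as those of STMN2 do. On the higher side, after the globins HBD and HBG1, stood VWA5A (3.18 ± 0.07), the alcohol dehydrogenase ADH1A (2.93 ± 0.06), the ephrin receptor EPHA5 (2.86 ± 0.08), the endothelin receptor EDNRB (2.83 ± 0.01), the antigen-presenting molecule CD1D (2.71 ± 0.10) and the cyclooxygenase PTGS1 (2.60 ± 0.01). On the lower side stood SBSPON (-4.82 ± 0.10), the limb regulator OSR2 (-4.77 ± 0.01), the tendon regulator MKX (-4.63 ± 0.17), HOXC10, STMN2, the secretory kinase partner FAM20A (-4.13 ± 0.01) and LY6K (-3.80 ± 0.07).

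Members of several gene families lay on one side. Of 16 protocadherin beta genes, neighbouring genes for neuronal adhesion proteins, 11 were higher in MRC-5 and 1 lower (median 0.69), with PCDHB5 at 3.39 ± 0.13, PCDHB9 at 1.54 ± 0.21 and PCDHB2 at 1.52 ± 0.04. All 9 measured pregnancy-specific glycoprotein genes were lower, led by PSG8 (-1.98 ± 0.03) and PSG7 (-1.94 ± 0.14), and all 10 metallothionein genes were lower, with MT2A at -1.29. With the olfactory receptor zero point the medians were 1.07, -0.88 and -0.45. PSG11 (-0.20 ± 0.04), MT1F (-0.23 ± 0.08) and MT1M (-0.32 ± 0.03) would turn positive there. Members of each family are similar in sequence, so their probes are not independent readings. The families were chosen because their members lay on one side, so no test of that is given. Of the other families, golgin A genes had a median of 0.44, with 15 of 22 higher and 5 lower. ZNF zinc finger genes had a median of 0.18, with 228 of 493 higher and 85 lower. With the olfactory receptor zero point the golgin A and ZNF medians were 0.82 and 0.56. Keratin-associated protein genes had a median of -0.36, with 1 of 42 higher and 26 lower, but a median of 0.0097 with the olfactory receptor zero point. Their quartiles, -0.477 and -0.165, lay close to those of the olfactory receptor genes, -0.515 and -0.205.

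The sign of the ratio was tested with the posterior HOX genes. If positive values meant more RNA in mix2, these genes, known from skin of the limbs and lower body, should lie above 0; the median of the 11 members past the test was -1.95, which argues against that sign. This is consistent with ratios of MRC-5 over mix2, as the titles read, though it assumes that the skin line brought these transcripts.

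The strongest positive ratios may come in part from single probes that read high in the Cy3 channel whatever the RNA. Of 119 probes at or above 3 on both arrays, 56 had other probes of the same gene; the median of those others was 0.089 (95% bootstrap interval -0.13 to 0.32), and 13 (23.2%) were at least 2-fold the same way. Of 76 such probes at or below -3, the median of the others was -1.42 (-2.09 to -0.80), and 42 (55.3%) were 2-fold the same way. The chromatin remodelling gene SMARCA4 shows the pattern, with probes at 4.02 ± 0.10, 0.08 ± 0.03 and -0.31 ± 0.03, as does the splicing factor RBM22, at 5.13 ± 0.06 and 0.16 ± 0.01. Transcript variants that only some probes detect stay open, and the dye cannot be separated from the cells without a dye swap. The probes of HBD and HBG1 concur, but globin genes share sequence, so their accord does not exempt them.

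The olfactory receptor zero point, chosen after the values were seen, does not by itself bring the cell cycle list to 0. The list median of -1.17 became -0.80 there. That follows from the shifts of 0.36 and 0.39 and is no separate test. Against artefacts of single probes, 87.5% of the cell cycle genes with several probes (7 of 8, all except CCNB2) had every probe below 0. This count holds at the deposited zero point, where the olfactory receptor genes themselves had a median of -0.37. It was not made with the olfactory receptor zero point, where a probe with a small negative ratio would turn positive. Among genes with several probes on one side of 0, the 7 members left had a median of -1.23. That filter drops CCNB2 for its probe above 0, so a median below 0 is built in. The list missed the threshold there with camera in limma (adjusted p = 0.0712), and members with 1 probe have no such check. A slower-growing MRC-5 culture, a difference between the lines, and differences in culture state or passage, which the labels do not give, stay open and were not tested.

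The small negative values of markers of other cell types may reflect an offset shared by dim probes. The median of 70 markers from 5 lists was -0.35, within the quartiles of the olfactory receptor genes (-0.515 and -0.205). By list, the medians of neural (-0.44), immune (-0.26) and endothelial markers (-0.22) lay within them, that of epithelial markers (-0.521) lay just below and that of pericyte and adipocyte markers (-0.13) above, so an offset may account for part of the pattern only. Such an offset would also place unexpressed genes among the 6978 lower calls: 76 of 114 olfactory receptor genes passed on the lower side, against 6978 of all 18592 genes. KRT19 lies far beyond it.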
